A study of Mus musculus with 6 samples.

How the data were processed

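RNA was measured on Illumina mouse bead arrays, which report 1 signal per probe from many beads that carry the same oligonucleotide. The cells were lymphocytes released mechanically from the thymus of mice aged 8 to 12 weeks on a mixed C57/bl6-129sv background, per the labels' protocols. No sort or gate is named in the labels, so the preparations can hold other cells of the thymus. Of the 6 arrays, 3 came from mice with KAP1 (gene symbol Trim28) deleted in the T lineage by a floxed allele and CD4-Cre, and 3 came from littermate controls. Each array stands for 1 mouse, so the spread within a group is a spread between animals. How many floxed copies each control carried, whether any control carried CD4-Cre, and which exons are removed, are not given in the sources used here.

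The deposited table of probe signals holds intensity values on a linear scale that were not normalized between arrays, per the file headers. A detection p-value for each probe and array stands beside each intensity, per the file headers. The submitters' processing notes name BeadStudio 3.1.3, and its settings are not given in the sources used here. The authors' processed value table holds intensity values of the same 6 arrays. On each array it ranked the 45281 probes as that array's own signal did, with a Spearman coefficient of 1.0, against at most 0.84 for any other array. Its medians lay between 6.43 and 6.50 and its maximum was 48108.9 on every array, and 34.3% to 34.4% of the values were below 0. From these values it is linear, background-subtracted and equalized between arrays, and it was not centred by gene. The steps that made it are not given in the sources used here. It was used as an alternative, with values below 0 set to 0 before the offset of 16 was added.

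Values were computed from the table of probe signals with limma 3.58.1 in R 4.3.3. The neqc function estimated the background of each array from the detection p-values, corrected it with a normal-exponential model, equalized the arrays by quantiles and took log2 after adding 16. A log2 difference between groups is therefore on the scale of the corrected signal plus 16, which understates the change of dim probes. A probe was called detected on an array at a detection p under 0.01. A probe was tested when it was detected on at least 3 of the 6 arrays, which left 14651 probes. Before normalization the mean signal ran from 340.1 on control replicate 6 to 678.5 on knockout replicate 1. Between 13973 and 15182 probes were detected per array, 30.9% to 33.5% of all probes. The number of arrays limits the precision: the median standard error of a log2 difference was 0.257.

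Probe names came from an annotation table of the array, with gene numbers looked up in the mouse assembly GRCm38.p6, which matched 34807 probes. In all, 34885 probes had 1 gene symbol, 18 had several and 10378 had none, and no gene was named from a probe with several. The tested probes covered 8200 named genes, and 2192 tested probes had no symbol. The assembly was used for names and for the order of genes along chromosomes alone. Probe sequences were not used here, so a probe of a gene family with near-identical members is not shown to be specific to the gene it is named for.

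The only comparison the design states is knockout against control. It was fitted for each probe with lmFit and eBayes in limma, with 3 arrays per group, no covariate and a constant prior, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes with a threshold of 0.05. The fit had 4 residual degrees of freedom and 4.51 prior degrees of freedom. All p-values are two-sided. A probe detected on no array of one group has only a bound there. Its fold is given as "at least", the mean of the bright group against the mean, in the other group, of the higher of the probe's own value and the lowest value of a detected probe on that array.

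Gene lists were tested with limma's camera function, which asks whether a list's genes moved relative to all other genes. Each gene was represented by its tested probe with the highest mean over the 6 arrays, and the correlation between genes was preset to 0.01. Of 41 lists, 34 had at least 5 tested genes, and p-values were adjusted over these 34. Members were also tested with p-values adjusted over the list alone. The same lists were tested with a correlation estimated for each list, and with fry, which tests whether a list's genes move one way or in either direction without comparing them with other genes. The standard error of a list's mean is that of the difference between the groups' array means, with 3 arrays each. Of 1575 list symbols, 5 matched no gene name.

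The groups, the tests, the lists, the alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule names Trim28, up to 15 genes with the largest rise and 15 with the largest fall past the threshold, and members of the lists. Because fewer than 10 genes passed, its fallback names the 10 genes with the smallest p, whether or not they passed. It adds up to 4 members of each list past the threshold, or the 2 members with the smallest p of a shifted list that had none. The rule for rises and falls leaves out clone names, and 4930550C14Rik is named by the fallback. Genes outside this rule are said to have been chosen after their values were seen.

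The alternatives were no background correction, a normal-exponential correction with an offset of 50, cyclic loess, median scaling, offsets of 1 and 50, 3 other filters on dim probes, the authors' value table, a prior with an intensity trend, array weights, each array left out in turn, sex-linked transcripts left out and a fold minimum of 1.5. For the lists they were also the estimated correlation, fry and the mean of all probes of a gene. Added after seeing the data were a block for pairs of animals, a block for cohort, the first cohort alone, a covariate for antigen-presenting cells and a list of histone genes by current symbols. The pairs and cohorts are an inference: a second header line of the signal table gives a number for each animal, and each knockout lies within 1 or 2 of 1 control. These pairs are knockout replicate 1 with control 4, 2 with 5 and 3 with 6, and the last pair has numbers far from the other 4 animals. The labels state no pairs. The correlation of deviations from the group means was 0.128, 0.164 and 0.518 within the pairs, although knockout replicate 2 correlated more with control 4 (0.317) than with its own neighbour.

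The fit was tested on simulated data for the comparison of knockout with control, with 14651 probes and 200 changed probes in each of 20 runs. It recovered 10.1% of changes of 1 on the log2 scale, 81.5% of changes of 2 and 96.2% of changes of 3. Of its calls, 4.8% were false, and 0 had the wrong sign. The simulated noise was independent between probes and arrays. With 200 changed probes the adjusted threshold is also easier to pass than in the real data, where 4 probes passed. The shares recovered are therefore not shown to hold for the real arrays. Of lists shifted by 0.4 in these runs, 86% were found where genes varied independently, with 0.3 false lists per run. Figures were drawn with matplotlib 3.10.9.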

Results

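The expression of 45281 probes was measured in thymic lymphocytes of 3 mice that lacked KAP1 in the T lineage and of 3 littermate controls. KAP1, encoded by Trim28, is a corepressor that KRAB zinc finger proteins bring to chromatin, where it works with histone methyltransferases and heterochromatin proteins. CD4-Cre acts from the stage at which thymocytes carry both CD4 and CD8. The comparison addresses which transcripts differ in T cell progenitors when KAP1 is removed. Between 13973 and 15182 probes were detected per array, and 14651 probes entered the test. The Y-linked genes Eif2s3y and Kdm5d were detected on all 6 arrays, with log2 differences of 0.10 ± 0.19 and 0.16 ± 0.25 (SE, n = 3 per group) between knockout and control.

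Trim28 itself was lower in the knockout on every array. Its only probe, ILMN_1227225, had a log2 signal of 10.69 ± 0.41 in the knockout and 12.41 ± 0.17 in the controls (SD, n = 3 each), a 3.30-fold difference. The 3 knockout arrays lay between 10.23 and 11.01 and the 3 control arrays between 12.25 and 12.59. The log2 difference was -1.72 (SE 0.26, 95% interval -2.31 to -1.14), and it did not pass the threshold over all probes (limma adjusted p = 0.23). Whether the probe lies inside the deleted part of the gene is not given in the sources used here, so its residual signal cannot be read as a share of undeleted cells.

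A small number of transcripts rose in the knockout, and by large factors. Vmn1r65, a vomeronasal receptor gene (probe ILMN_2971043), rose 7.85-fold, from a log2 signal of 6.70 ± 0.26 to 9.67 ± 0.17 (SD, n = 3 each; limma adjusted p = 0.00815). The transcript 4930550C14Rik, known by a clone name (probe ILMN_1250814), rose 4.46-fold, from 5.97 ± 0.23 to 8.13 ± 0.18 (limma adjusted p = 0.0308). Rbpms2, an RNA-binding protein gene (probe ILMN_2621012), was detected on the 3 knockout arrays and on 0 control arrays, and rose at least 3.47-fold to 7.30 ± 0.53 (limma adjusted p = 0.0308). Probe ILMN_1218717, which has no gene symbol here and is named after its values were seen, rose 4.99-fold, from 7.34 ± 0.26 to 9.65 ± 0.30 (limma adjusted p = 0.0308).

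**Figure D1:**
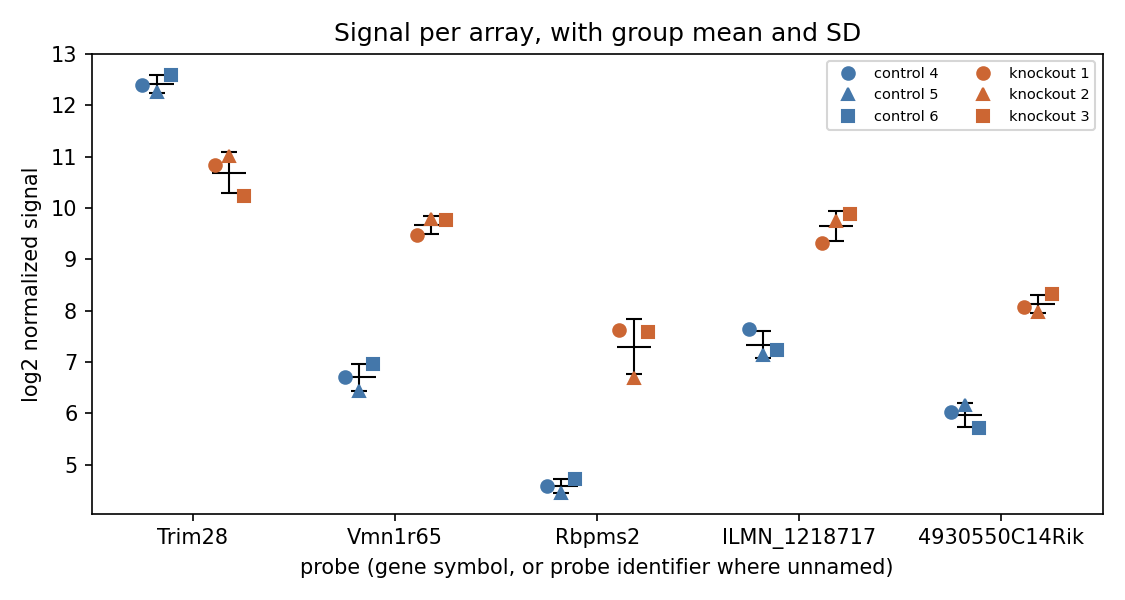
Log2 normalized signal (vertical axis) of Trim28 and of the 4 probes past the threshold, 1 symbol per array, with the group mean and SD (n = 3 each) in black; blue is control and orange is knockout. Trim28 lies at 10.69 in the knockout and 12.41 in the controls, and Vmn1r65 at 9.67 and 6.70, with no overlap between the groups for any of the 5 probes.

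These 4 probes were all that passed the threshold among 14651, and 0 probes fell in the limma fit, against 189 lower at an unadjusted p under 0.05 and 1 lower (Trim28) with a prior that both follows intensity and is robust to outliers. All 4 were higher in the knockout within each of the 3 pairs of animals with neighbouring numbers, which follows from groups that do not overlap. The differences within pairs ran from 2.77 to 3.34 on the log2 scale for Vmn1r65, from 1.82 to 2.61 for 4930550C14Rik and from 1.69 to 2.65 for ILMN_1218717, and Rbpms2 has only its bound. With these pairs as a block, Vmn1r65 and Rbpms2 passed and the count was 2. Leaving out 1 array left 0 probes past the threshold for knockout replicates 1 and 3 and control replicates 4 and 5, Rbpms2 for knockout replicate 2 and Vmn1r65 (3.12) for control replicate 6. The log2 differences were then 2.84 to 3.12 for Vmn1r65, 2.06 to 2.25 for 4930550C14Rik and 2.21 to 2.46 for ILMN_1218717, and with a covariate for antigen-presenting cells 0 probes passed, at 2.70 for Vmn1r65, 2.38 for 4930550C14Rik and 1.96 for ILMN_1218717.

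Across all tested probes few differences stood out in the fit without pairs. At an unadjusted p under 0.05 there were 518 probes, 329 higher and 189 lower, where 733 would be expected with no difference. With pairs as a block this count was 826 and with cohort as a block 781, and without 1 array it ran from 317 (control replicate 6) to 846 (knockout replicate 1). The groups did not overlap for 1120 probes, 7.64% of those tested, where chance gives 10% for arrays that vary independently. Genotype parts all 3 inferred pairs of animals. Deviations from the group means correlated by 0.518 in the pair of the second cohort. In the pairs of the first cohort they correlated by 0.128 and 0.164, against 0.317 and -0.042 for its other combinations of knockout and control. A correlation by pair is thus not told apart from one by cohort. The arrays are not shown to vary independently, so this share is not shown to lie below chance. A difference of at least 2-fold was seen for 130 probes, 100 of them higher in the knockout and 30 lower. The first principal component, with 42.7% of the variance, set knockout replicate 2 (-49.86) and control replicate 4 (-17.69) against knockout replicate 3 (29.69) and control replicate 6 (38.87). Knockout replicate 1 (-0.43) and control replicate 5 (-0.58) lay between them. The component did not follow genotype, and it set the inferred second cohort, knockout replicate 3 and control replicate 6, above every array of the first.

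The genes with the next smallest p included germ cell, homeobox and linker histone genes, and none of them passed the threshold. Nkx2-4, a homeobox transcription factor gene, Tdrd9, a helicase gene of the germ cell piRNA pathway, and H1f1, a linker histone gene, were detected on the 3 knockout arrays and on 0 control arrays. Their levels were at least 1.48-fold, 1.37-fold and 1.66-fold higher in the knockout (limma adjusted p = 0.201, 0.23 and 0.327). The other Nkx2-4 probe, detected on 1 array, differed by -0.27. The linker histone gene H1f5 differed by 1.36 ± 0.24 on the log2 scale (SE, limma adjusted p = 0.401). Snai3, a Snail family transcription factor gene, differed by 1.25 ± 0.21 (limma adjusted p = 0.396), and Il18r1, which encodes a chain of the interleukin 18 receptor, by 1.57 ± 0.28 (limma adjusted p = 0.401). The other Il18r1 probes, both detected on 0 arrays, differed by 0.08 and 0.21. Nkx2-4 and Tdrd9 passed with an offset of 1 and in the authors' value table.

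Genes of antigen presentation and of B cells and macrophages were higher in the knockout as groups with the preset correlation. None of these lists passed with an estimated one. The list of dendritic cell and MHC class II genes had 19 tested members, of which 17 were higher, with a mean log2 difference of 0.62 ± 0.23 (SE, n = 3 per group; camera in limma, adjusted p = 2.59e-11; adjusted p = 0.363 with an estimated correlation). Its MHC class II genes H2-Aa and H2-Eb1 differed by 1.21 ± 0.28 and 1.11 ± 0.27. Adjusted over the list alone, 5 members passed (H2-Aa, H2-Eb1, H2-Ab1, H2-DMa and H2-DMb1), and adjusted over all genes 0 did. The B cell list was higher for 6 of 7 genes, by 0.53 ± 0.21 (adjusted p = 0.000229; adjusted p = 0.363 with an estimated correlation). In it Blk, a kinase gene of B cells, and Cd79b, a part of the B cell receptor, differed by 0.83 ± 0.28 and 0.62 ± 0.28, and the other tested Blk probe by 0.23. The macrophage list was higher for 14 of 15 genes, by 0.32 ± 0.23 (adjusted p = 0.00149; adjusted p = 0.421 with an estimated correlation). Its members Mpeg1, a pore-forming protein gene of macrophages, and Csf1r, the receptor gene for macrophage colony-stimulating factor, differed by 0.85 ± 0.31 and 0.54 ± 0.32, with Csf1r at 0.88 without control replicate 4 and 0.30 without control replicate 6. Without knockout replicate 2 the B cell list was at 0.36 and the macrophage list at 0.22, and neither passed. Without control replicate 4 or 6 the macrophage mean was 0.51 or 0.21.

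Lists of mature and specialised T cells also stood higher with the preset correlation, and none of them passed with an estimated one. The list of mature single-positive and egress genes was higher for 27 of 31 genes, by 0.38 ± 0.16 (camera in limma, adjusted p = 1.57e-07; adjusted p = 0.363 with an estimated correlation), and by 0.24 without knockout replicate 2. Its members Itgae and Itgb7, which encode the 2 chains of the integrin that binds E-cadherin, differed by 1.20 ± 0.34 and 0.85 ± 0.30, and the other 3 tested Itgae probes by 0.48, 0.69 and 1.26. The regulatory T cell list was higher for 11 of 13 genes, by 0.37 ± 0.23 (camera adjusted p = 0.00149, and 0.421 with an estimated correlation). Its members with the smallest p were Ctla4, at 0.74 ± 0.36, and Itgae again, and both are also in another list. The regulatory T cell transcription factor genes Foxp3 and Ikzf2 were its 2 lower members, at -0.14 ± 0.21 and -0.08 ± 0.26, and Il2ra was at 0.01 ± 0.27. The shift of this list is therefore not shown to be one of regulatory T cells. The list of effector cytokines and helper T cell genes was higher for 5 of 5 genes, by 0.64 ± 0.50 (adjusted p = 0.00149; adjusted p = 0.421 with an estimated correlation). In it the chemokine gene Ccl4 was 2.01-fold higher and the cytokine gene Tnf differed by 0.54 ± 0.28 on the log2 scale, with their other tested probes at 0.58 and 0.32. The innate-like T and NK cell list was higher for 9 of 10 genes, by 0.45 ± 0.21 (adjusted p = 0.00282; adjusted p = 0.421 with an estimated correlation), with the chemokine receptor gene Cxcr6 at 0.66 ± 0.36 and the receptor gene Cd160 at 0.71 ± 0.39. Without knockout replicate 2 these 3 lists were at 0.19, 0.23 and 0.25, and none passed, with Tnf at 0.33 and Cd160 at 0.27. Within the pairs Cd160 differed by 0.10, 1.92 and 0.12, and Ctla4 was at 0.33 without control replicate 6.

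The Gimap family, GTPase genes of lymphocytes, was higher for 6 of 6 genes, by 0.32 ± 0.13 (camera in limma, adjusted p = 0.00803; adjusted p = 0.421 with an estimated correlation), with Gimap7 at 0.60 ± 0.23 and Gimap5 at 0.46 ± 0.29 (0.25 without knockout replicate 3, 0.70 without control replicate 6, and 0.30 for its other tested probe). Its difference was 0.32, 0.33 and 0.29 within the 3 pairs of animals, and it did not pass without knockout replicate 3 (0.23) or control replicate 4 (0.25). The MHC class I list was higher for 10 of 12 genes, by 0.33 ± 0.27 (adjusted p = 0.00832; adjusted p = 0.545 with an estimated correlation). Its members with the smallest p went opposite ways, H2-T10 at -0.62 ± 0.29 (-0.37 without control replicate 4, its other probes at -0.35 and 0.04) and H2-M2 at 1.06 ± 0.57. Within the pairs H2-M2 differed by 1.04, 2.83 and -0.69, and it was 0.45 without knockout replicate 2 and 1.61 without control replicate 6. The list did not pass without knockout replicate 2 (0.07) or control replicate 4 (0.33), nor with array weights (0.23). The type I interferon list was higher for 23 of 29 genes, by 0.18 ± 0.27 (adjusted p = 0.0133; adjusted p = 0.702 with an estimated correlation), with the antiviral genes Ddx58 at 0.44 ± 0.22 and Rsad2 at 0.71 ± 0.37 (0.45 without knockout replicate 2 and 0.37 without control replicate 6). It turned to -0.03 without knockout replicate 2 and was 0.05 without control replicate 5, past the threshold in neither case, and it was 0.29, 0.28 and 0.35 without knockout replicate 1, knockout replicate 3 and control replicate 4. The T cell receptor signalling list was higher for 25 of 37 genes, by 0.12 ± 0.09 (adjusted p = 0.028; adjusted p = 0.698 with an estimated correlation), with the kinase genes Tec at 0.62 ± 0.24 and Fyn at 0.60 ± 0.26. It did not pass without knockout replicate 1 (0.11), knockout replicate 3 (0.05) or control replicate 4 (0.11), nor with the mean of all probes of a gene (0.09) or in the first cohort alone (0.04), and it was 0.20 without knockout replicate 2. The histone list, under the pattern of symbols used, was higher for 4 of 6 genes, by 0.51 ± 0.09 (camera adjusted p = 0.00144, and 0.363 with an estimated correlation). Its median was 0.24, and H1f1 and H1f5 were its 2 members past the threshold when adjusted over the list alone. Its mean includes H1f1, which was detected on 0 control arrays and has only a bound. The mean was 0.24 without background correction and 0.28 with no filter on dim probes, and the list passed each time.

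Cell cycle genes were lower in the knockout as a group with the preset correlation of 0.01. The correlation estimated for this list was 0.389, and with it the list did not pass. Of 41 tested genes 39 were lower, with a mean log2 difference of -0.47 ± 0.29 (SE, n = 3 per group; camera in limma, adjusted p = 2.8e-12; adjusted p = 0.421 with an estimated correlation). The cell cycle transcription factor genes Foxm1 and E2f2 differed by -0.72 ± 0.21 and -0.72 ± 0.23. The list was lower in all 3 pairs of animals, by -0.33, -0.26 and -0.83, and by -0.20 without knockout replicate 3. The neutrophil list was lower for 7 of 8 genes, by -0.42 ± 0.35 (adjusted p = 0.00803; adjusted p = 0.421 with an estimated correlation), with the granule protein genes Camp at -0.93 ± 0.34 (-0.56 without knockout replicate 3) and Ngp at -0.51 ± 0.25. It did not pass without knockout replicate 3 (-0.18) or control replicate 4 (-0.17). The list of heterochromatin genes and KAP1 partners was lower for 18 of 19 genes, by -0.19 ± 0.11 (adjusted p = 0.00997; adjusted p = 0.421 with an estimated correlation). Its members with the smallest p were Uhrf1 at -0.78 ± 0.28 and Dnmt1 at -0.57 ± 0.30, which maintain DNA methylation behind the replication fork, and which were at -0.51 and -0.33 without knockout replicate 3. It did not pass without knockout replicate 2 (-0.12) or 3 (-0.15), with array weights (-0.14) or in the first cohort alone (-0.15), and it was -0.30 without knockout replicate 1.

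**Figure D2:**
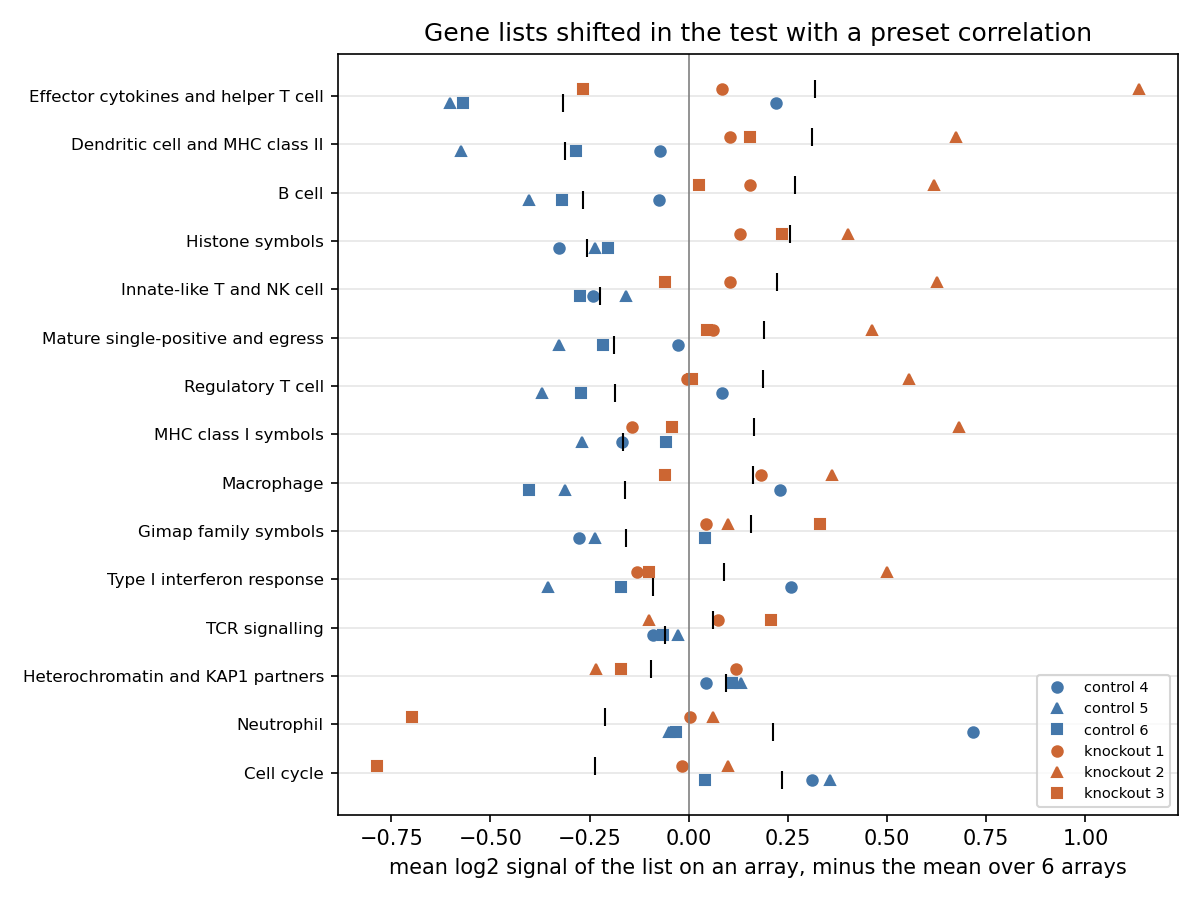
Mean log2 signal of each of the 15 shifted lists on each array, minus the mean over 6 arrays (horizontal axis); blue is control, orange is knockout, and a black bar marks the group mean (n = 3 each). Knockout replicate 2 has the highest value of all arrays for the effector list (1.14) and the dendritic cell list (0.67), and knockout replicate 3 the lowest for the cell cycle list (-0.79).

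In all, 15 of 34 lists shifted with the preset correlation, 12 higher and 3 lower, and 0 shifted with an estimated correlation in camera, where 4 had an unadjusted p under 0.05. By fry 0 lists shifted in one direction and 1, the histone list, when members could go either way. Of the shifted lists 7 had 1 pair of animals that went the other way. In the pair of knockout replicate 1 these were the effector (-0.14), interferon (-0.39), regulatory T cell (-0.09), macrophage (-0.05) and heterochromatin (0.08) lists, and in the pair of knockout replicate 2 the T cell receptor signalling (-0.07) and neutrophil (0.11) lists. Without knockout replicate 2 the count was 8. With no filter on dim probes it was 11, and the effector list (0.13), the innate-like list (0.12), the MHC class I list (0.14) and the interferon list (0.13) no longer passed.

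The lists of KRAB zinc fingers, germline genes, and double-negative and double-positive thymocytes did not shift in the comparison without covariates. The KRAB zinc finger list had 36 of 71 genes higher and a mean log2 difference of 0.02 ± 0.08, and with the covariate for antigen-presenting cells, chosen after seeing the data, it passed at 0.20. All genes with a numbered Zfp symbol had 77 of 175 higher and a mean of -0.01 ± 0.09. The genes beside Trim28 had a mean of -0.03 ± 0.11. Imprinted genes were at 0.10 ± 0.06, and germline genes at 0.09 ± 0.05, with Tdrd9 past the threshold when adjusted over the list alone. Among lists of T cell stages and signals, double-positive genes were at -0.05 ± 0.16, double-negative genes at 0.02 ± 0.18, positive selection genes at 0.16 ± 0.10, TGF-beta genes at 0.03 ± 0.11 and cytokine receptor genes at 0.12 ± 0.08. Il18r1 passed when adjusted over the last list alone. Apoptosis genes were at 0.15 ± 0.06 and p53 targets at -0.03 ± 0.12. Immediate early genes were at 0.02 ± 0.14, glucocorticoid response genes at 0.15 ± 0.13, unfolded protein response genes at -0.06 ± 0.02 and thymic epithelium genes at -0.01 ± 0.12. Ribosomal protein, mitochondrial genome and proteasome genes were at 0.07 ± 0.09, 0.16 ± 0.15 and 0.04 ± 0.16. Glucocorticoid response genes passed without knockout replicate 2 (0.26) or control replicate 6 (0.20) and with array weights (0.26). Ribosomal protein genes passed without knockout replicate 1 (0.11), with no background correction (0.07), with cyclic loess (0.08) and with median scaling (0.10). With the covariate for antigen-presenting cells, which overlaps with genotype, glucocorticoid response genes passed at 0.37. Double-positive genes (0.34), p53 targets (0.28), numbered Zfp genes (0.17) and proteasome genes (-0.23) then passed with their sign reversed. The lists of gamma-delta T cells, erythroid cells, fibroblasts, endothelium, adipocytes, sex-linked transcripts and T cell receptor segments had 4, 3, 4, 4, 2, 3 and 4 tested genes and were not tested.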

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

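The block for pairs, the block for cohort, the first cohort alone, the covariate for antigen-presenting cells and the histone list by current symbols were chosen after seeing the data. The count of 4 changed probes, all higher, became 2 without background correction, 1 with no filter on dim probes, 6 in the authors' value table, 2 with pairs by animal number as a block, 0 in the first cohort alone and 0 with the covariate; leaving out 1 array gave 0 to 1. Vmn1r65, 4930550C14Rik and ILMN_1218717 were then at 3.11, 1.98 and 2.17 in the first cohort and at 2.70, 2.38 and 1.96 with the covariate. The 6 probes were the same 4 with Nkx2-4 and Tdrd9 added. With no filter 45281 probes were tested and the adjustment was heavier. With a left-out array, the first cohort alone or the covariate, fewer degrees of freedom were left. The covariate was also higher on all 3 knockout arrays than on any control array, which widens the error of the genotype difference. The cause of the other changes was not tested. The count of lower probes went from 0 to 1 with a trend and robust prior, where Trim28 passed at -1.72 (limma adjusted p = 0.0308; 0.0308 to 1 over all alternatives). Trim28 kept its sign in all 23 alternatives, between -1.41 and -2.10, and Vmn1r65 kept its sign in all 23 and lost its call in 7. 4930550C14Rik and ILMN_1218717 each lost it in 11 of 23 and Rbpms2 in 13 of 22, among them no background correction, cyclic loess, median scaling and an offset of 50. As Rbpms2 was undetected in the controls, its size depends on the background step and offset, from 1.07 to 3.99.

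The count of 15 shifted lists became 0 with an estimated correlation, 0 with fry, 11 with no filter on dim probes, 10 with the covariate, and 8 to 16 without 1 array. With no filter the effector list went from 0.64 to 0.13, the innate-like list from 0.45 to 0.12, the MHC class I list from 0.33 to 0.14 and the interferon list from 0.18 to 0.13, and none of the 4 passed. Calls were gained by the apoptosis list with a detection limit of 0.05 (0.17), by the positive selection (0.22) and immediate early (0.22) lists in the first cohort alone, and by the glucocorticoid (0.37) and KRAB zinc finger (0.20) lists with the covariate. With it the innate-like (0.08), B cell (0.02), histone (0.39) and Gimap (0.37) lists lost theirs, and the dendritic cell list, which is the covariate, is 0 by construction. The type I interferon list ran from -0.0254 to 0.3517 over the left-out arrays, and reversed without knockout replicate 2. With the covariate, double-positive genes reversed to 0.34, mature single-positive genes to -0.0443, p53 targets to 0.28, interferon genes to -0.54, regulatory T cell genes to -0.22, effector genes to -0.57, heterochromatin genes to 0.0094, macrophage genes to -0.11, numbered Zfp genes to 0.17, MHC class I genes to -0.27 and proteasome genes to -0.23. Of these, double-positive, p53 target, numbered Zfp and proteasome genes passed with the covariate without passing in the main fit, and interferon genes passed in the opposite direction. The covariate comes from the same arrays and was higher on all 3 knockout arrays than on any control array. These values therefore do not separate it from genotype. The cause was not tested. Neither block changed the call of a list, and the pairs as a block ended the calls of 4930550C14Rik and ILMN_1218717 alone among the probes named. Of 864 comparisons of named probes with an alternative, 817 stayed on their side of the threshold, 42 lost and 5 gained a call, and 0 with a call on either side reversed. Of 882 for the lists, the numbers were 797, 61, 12 and 12. A slide term was not run because no slide position was used here.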

Other observations

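The tests of antigen-presenting against neutrophil genes, of replication genes, of the chromosome of 4930550C14Rik and Rbpms2 and of splits for the probes were chosen only after the result was seen. The genes of this paragraph were chosen after their values were seen, and none passed the threshold over all probes. Cldn10, which encodes a tight junction protein, was higher in the knockout by 0.97 to 1.24 on the log2 scale with 3 tested probes, and the groups did not overlap for any of them (limma adjusted p = 0.417 to 0.915), while its 2 untested probes differed by 0.02 and 0.12. The predicted gene Gm4956 was higher by 1.51 and 1.57 with both its probes (limma adjusted p = 0.417 to 0.637). Sytl3, a gene of vesicle transport, was higher by 1.07 to 1.35 with 3 tested probes (limma adjusted p = 0.401 to 0.998). Zfp760, a KRAB zinc finger gene, was higher by 1.25 ± 0.26 (SE, limma adjusted p = 0.673) while its list as a whole had a mean of 0.02. For Cldn10, Gm4956, Sytl3 and Zfp760 the knockout was above the control with every tested probe in each of the 3 pairs of animals. The groups did not overlap for any of these probes, so the pairs add no support of their own. Traf1 and Trmt1l, higher by up to 1.07 and 1.27, were not higher in every pair with every probe.

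For the count of changed probes, 1 of the 10 splits of the 6 arrays into groups of 3 gave as many as 4, the real one, and the highest of the other splits gave 0. For the lists, 2 of the 10 splits shifted as many as 15, and the highest other, knockout replicate 1 with control replicates 5 and 6 against the rest, shifted 16. That split parts all 3 pairs of animals, as the real one does, and the other splits that part all 3 shifted 7 and 12 lists. With 10 splits the share cannot go under 0.1, so these splits are too few for a test. At an unadjusted p under 0.05, the split of knockout replicates 1 and 2 with control replicate 4 gave 1534 probes and that of knockout replicates 1 and 3 with control replicate 6 gave 1453, against 518 for genotype, and both part only 1 pair of animals. The other splits that part all 3 pairs, as genotype does, gave 130, 392 and 652.

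Vmn1r65, 4930550C14Rik and Rbpms2 rose far more than the tested genes nearest to them. Genes too dim to be tested were not looked at, so a change shared with such neighbours stays open. If the change spread along the chromosome, neighbours would be higher too, but the 30 nearest tested genes, 5 on each side of each gene in GRCm38.p6, had a median log2 difference of -0.05, at the 24.6th percentile of 10000 random sets of windows. A chromosome segment that came with the floxed Trim28 allele from another strain is argued against for 4930550C14Rik and Rbpms2, since 0 of these 2 genes lie on the chromosome of Trim28. The background is mixed, and a segment on another chromosome that differs between the groups was not tested for these 2 genes. A single segment of that kind could hold both, so the 2 genes are not shown to be separate cases. Vmn1r65 lies within 20 tested genes of Trim28, where 3 of 40 genes had an unadjusted p under 0.05, the 82nd percentile of windows of that size; such a segment could differ at few genes, so this count leaves it open and it cannot be told apart from loss of KAP1 for Vmn1r65. Loss of repression by KAP1 at these genes may be a further explanation, which was not tested, and ILMN_1218717 has no position here.

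Antigen-presenting cell, B cell and mature T cell lists were higher and the cell cycle list lower in the knockout with the preset correlation. None of them passed with an estimated correlation. A lower share of thymocytes would raise every other cell type alike. Dendritic cell and MHC class II genes moved apart from neutrophil genes by 1.05 (95% interval 0.30 to 1.80). The abundant Cd74 was at 0.68 ± 0.28 and S100a8 at -0.33 ± 0.59 (SE). Without knockout replicate 2, control replicate 4 or control replicate 5 the interval without pairs held 0 (-0.09 to 2.09, -0.05 to 1.88 or -0.07 to 2.15). Within the 3 pairs of animals, a check added after the result was seen, the difference was 0.89, 1.14 and 1.11 (95% interval 0.71 to 1.38). The dendritic cell and neutrophil lists were compared after they had been seen to go opposite ways, so neither interval can decide on this explanation. More antigen-presenting cells as the whole cause could not be decided: with their score as a covariate the cell cycle list was at -0.74, with an interval from -2.44 to 0.95, and the mature single-positive list at -0.04 (-0.24 to 0.15). Of the 19 dendritic cell genes and the 7 B cell genes 3 and 1 are in another list, no sort is named that would remove such cells, and without knockout replicate 2 the dendritic cell list was at 0.44 and the B cell list at 0.36. A change of the thymocytes through loss of KAP1 stays open and was not tested apart from composition.

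A wider list of histone genes, which holds H1f1, H1f5, H1f2 and H1f10 of the 6 under the pattern fixed beforehand, had a positive mean. It did not pass with an estimated correlation. By current symbols, a list chosen after seeing the data, 38 of 50 histone genes were higher and 12 had an unadjusted p under 0.05, all 12 higher, with a mean log2 difference of 0.50 ± 0.37 (SE, 95% interval -0.53 to 1.53; p = 0.198 with an estimated correlation in limma). More cells in S phase would raise replication genes as well, and all 14 of these were lower, by -0.62 on average, but the interval, with an upper bound of 0.77, holds 0 and the mean was -0.13 without knockout replicate 3, so this cannot be told apart. A single library could carry the difference, since the mean was 0.16 without knockout replicate 2, whose score of 0.92 above the mean of the arrays was the highest. The mean was 0.39 to 0.76 without each other array, and a standard error of 0.37 leaves this open. Within each inferred pair of animals the knockout's histone score was above its control's (0.11 and -0.18, 0.92 and -0.09, -0.28 and -0.47). Its replication score was below its control's each time (0.10 and 0.43, 0.26 and 0.37, -1.29 and 0.13). An effect of KAP1 loss on histone transcripts, or on their polyadenylation, may be a biological explanation and was not tested.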
